A study of Caenorhabditis elegans with 4 samples.

How the data were processed

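The series profiled by ChIP-seq where a GFP-tagged transcription factor, F23F12.9, sat on the genome of Caenorhabditis elegans embryos. Animals of strain OP327, which carries a tagged F23F12.9 transgene, were grown at 20 °C and fixed with 2% formaldehyde, per the labels' protocols. Tagged protein was collected with an anti-GFP antibody, and part of each extract was kept as input DNA. The labels give the strain's background allele in 2 different ways, so the strain name is as labelled and its genotype is not given here. The 4 samples form 2 groups by their titles: 2 ChIP samples (replicates 1 and 2) and 2 input samples (replicates 1 and 2). The titles number the replicates but do not say whether they came from separate cultures.

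The data were 3 peak lists, 1 for each ChIP sample and 1 that its authors call combined. Peaks were called with SPP and passed through IDR, a procedure that ranks peaks by how well replicates agree, per the file headers and source columns. Whether IDR removed any peak from the replicate lists is not known here. Most nuclear peaks of each replicate list had no partner in the other. Coordinates are on WormBase build WS220, per the file headers, and are given here 1-based and inclusive. Software versions, thresholds, read filters, read depth and the use of the input libraries are not given in the sources used here. The combined intervals have a most common width of their own (480 bp, against 384 and 600 bp in the replicates), so they are not copies of either list. Whether they were called on pooled reads is not given in the sources used here. No values of the input samples were analysed here. Since the lists hold no read counts, depth is unknown and no value below carries a depth-based limit.

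The authors deposited 1 score per peak, whose unit the file headers do not state. In the combined list every peak carries the same score, 3.85, so this score orders nothing there. Each peak name also holds a number, and no header calls it a rank. In both replicate lists the peaks tied at the highest score are exactly those with the lowest numbers (numbers up to 4605 in replicate 1 and up to 2598 in replicate 2). The number and the score had a Spearman rho of −0.99 in each list, across peaks. The deposited number was therefore used as the order of peaks, the lowest first. Scores were not compared between lists.

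All tests below were computed from the deposited intervals with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks on mitochondrial DNA were kept out of every comparison in the results, which cover the 6 nuclear chromosomes. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. The share of shared peaks was compared with 1000 circular shifts of the other list along each chromosome, which keep its spacing and widths. This is a one-sided permutation test, and the smallest p it can give with 1000 shifts is 0.001. Shifted means for bins of the peak order, and the test on simulated lists, used fewer shifts. Intervals of shares are 95% Wilson intervals and cover counting error only. Chromosome lengths were taken as the span up to the last peak of any list, 100.238 Mb in all. Combined peaks per chromosome were tested against these spans with two-sided exact binomial tests, Benjamini-Hochberg adjusted over the 6 chromosomes. The middle 33.3% of each span was tested in the same way.

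The tests were checked on simulated lists of the size of the real ones. With 20% of 13776 replicate 2 peaks planted in replicate 1, the shift test recovered 20.3%, and with 5% planted it recovered 5.11%. With none planted, p was 0.68. Chromosome I, with its weight raised 1.3 times before shares were rescaled, was called in 95.5% of 200 simulated combined lists of 2237 peaks. Its share of peaks therefore rose by less than 1.3 times. Some chromosome was called in 4% of lists without a change. Simulated peaks were placed independently of one another, as the binomial test assumes, so these rates need not hold for clustered peaks. Real combined regions lay closer together than uniform placement would put them, as given below.

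Tests had also been set up for gene positions, gene lists, sequence motifs and the transgene's own loci. They were not run: no WS220 sequence or annotation was used here, and the gene table at hand is of another build, WBcel235. That table served only to give the symbol of the tagged gene. Peaks are therefore named by position. By the rule fixed beforehand these are the 10 first combined peaks and the first on each chromosome; since the score is constant, the peak number set the order. The other settings, chosen before the data were examined, were a reciprocal overlap of 50%, midpoints within 100 bp, the better-ranked 50% of each list, lists of equal length, local shifts of 5 to 50 kb, peaks within 2 kb merged, and each replicate alone with its first 2237 nuclear peaks. A shortened replicate 1 list, an expectation from replicate peaks outside the combined list, and exchanges of 1 Mb bins among and within chromosomes were added after seeing the data.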

Results

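To find the genomic regions bound by F23F12.9 in embryos, chromatin of a strain expressing the GFP-tagged protein was precipitated with an anti-GFP antibody in 2 ChIP samples. The 2 input samples have no peaks of their own in what follows. F23F12.9 is the locus of zip-8, a gene of the basic leucine zipper (bZIP) class of transcription factors. The list of ChIP replicate 1 held 20902 peaks, of which 20879 were nuclear. The list of ChIP replicate 2 held 13801 peaks, of which 13776 were nuclear. The combined list held 2237 peaks, all nuclear, which formed 2203 distinct regions once overlapping intervals were joined. These regions covered 877 kb, or 0.875% of the nuclear span. Peaks covered 7.71% of the span in replicate 1 and 7.52% in replicate 2. Most replicate peaks had a fixed width, 384 bp for 98.3% of replicate 1 and 600 bp for 99.2% of replicate 2. In the combined list 66.3% of peaks were 480 bp wide, and the first 100 were narrower, with a median of 327 bp.

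The first comparison asked whether both ChIP samples marked the same places. Of the nuclear peaks of replicate 1, 26.1% (5452 of 20879; interval 25.5 to 26.7%) overlapped a peak of replicate 2. Of those of replicate 2, 41.6% (5729 of 13776; interval 40.8 to 42.4%) overlapped a peak of replicate 1. Circularly shifted lists gave means of 11.9% and 18.8%, so the observed shares were 2.19 and 2.21 times those of shifted lists. None of the 1000 shifts reached the observed share in either direction, where the highest were 12.5% and 19.8% (one-sided permutation test, p = 0.001 for each, the smallest it can give). Each list is a single sample, so these tests weigh places along the genome and not a spread between replicates. Whether the replicate lists had been cut by IDR is not known here. The shares are therefore not a measure of agreement among peaks that passed it.

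The overlap was concentrated at the head of each list. Among the best-ordered 5% of nuclear peaks, 940 of 1044 replicate 1 peaks (interval 88.1 to 91.7%) and 675 of 689 replicate 2 peaks (interval 96.6 to 98.8%) overlapped the other list. In the next 5% the shares were 70.8% and 85.1%. In the last 5% they were 12.8% (interval 10.9 to 14.9%) in replicate 1, where shifted lists gave 11.9%, and 28.9% (interval 25.7 to 32.4%) in replicate 2, where shifted lists gave 18.8%. In replicate 1 the interval included the value of shifted lists in 4 of the 20 bins, all among the last 6. In replicate 2 it did so in none of the 20 bins. Peaks of 1 list can overlap one another: all 13801 replicate 2 peaks formed 11431 distinct regions, and all 20902 of replicate 1 formed 19339. Peaks late in a list can thus share a partner with better-ordered ones, and the bins do not count separate places.

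**Figure D1:**
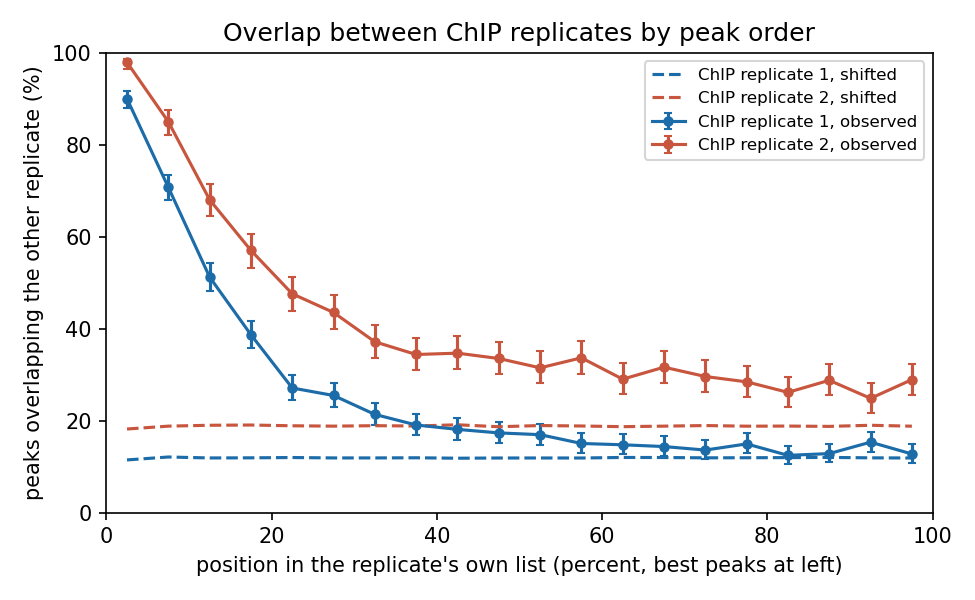
Share of nuclear peaks that overlap a peak of the other ChIP replicate (y axis, percent) in 20 equal bins of each replicate's own peak order (x axis, percent of the list, best at left). Points are observed shares with 95% Wilson intervals and dashed lines are means of circularly shifted lists; from the next 5% to the last, the observed shares fall from 70.8% to 12.8% in replicate 1 and from 85.1% to 28.9% in replicate 2.

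The order of peaks was shared in part. Of the first 100 nuclear peaks of replicate 1, 47 overlapped one of the first 100 of replicate 2, against a mean of 0.073% in shifted lists. For the first 1000 the share was 52.3% against 0.903%, and for the first 2237 it was 52.3% (interval 50.2 to 54.3%) against 2.08% (one-sided permutation test, p = 0.001 each, the smallest it can give). Across overlapping peaks the Spearman rho between the numbers of both lists was 0.507 over 5452 replicate 1 peaks and 0.495 over 5729 replicate 2 peaks. Where several peaks of the other list overlapped, the lowest number was used. Shifted lists gave overlaps for 11.9% of replicate 1 and 18.8% of replicate 2 peaks, so some pairs may overlap by placement alone. These rho values are across peaks, which are not independent replicates. None of the first 100 nuclear peaks of replicate 1 lacked a partner anywhere in the replicate 2 list. Among the first 100 of replicate 2, 2 lacked one in replicate 1. Of these, the peak at chromosome III 6478281 to 6478531 was number 13 in replicate 2, and the peak at chromosome II 11535580 to 11535735 was number 98. The nearest replicate 1 peaks began 82 and 188 bp farther on. Both peaks were named after their values were seen.

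**Figure D2:**
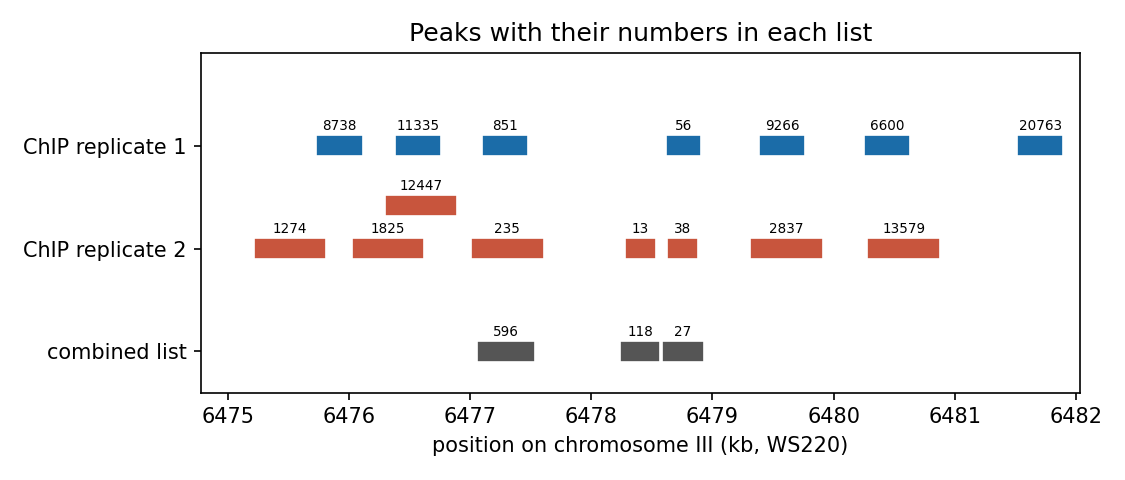
Peaks around the chromosome III peak that is number 13 in replicate 2 (x axis, position in kb, build WS220; y axis, the 3 lists). Boxes are peaks drawn to scale with their numbers in each list, and 1 replicate 2 peak is raised only for legibility; no replicate 1 peak lies over number 13, and combined peak 118 does.

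The combined list was then set against each replicate. Of its 2237 peaks, 2234 (99.9%) overlapped a replicate 1 peak and 1952 (87.3%; interval 85.8 to 88.6%) overlapped a replicate 2 peak. Both replicates held 1949 of them (87.1%), replicate 1 alone held 285, and replicate 2 alone held 3. The combined and replicate lists come from the same experiment, so this overlap is not independent evidence of reproducibility. Among the combined peaks, 88.3% met one of the first 2237 entries of replicate 1, and 60.9% one of the first 2237 of replicate 2. Of the 5452 nuclear replicate 1 peaks shared with replicate 2, 38.3% were in the combined list, against 2.09% of the 15427 that were not shared. For replicate 2 these shares were 39.8% of 5729 and 0.323% of 8047. With a reciprocal overlap of 50% the combined peaks found in replicate 2 fell to 59.7%.

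The first combined peak lay on chromosome II at 2997558 to 2998439 and was 882 bp wide. It was number 1 in both replicates. The second lay on chromosome III at 3377113 to 3377516, where the replicate numbers were 2 and 10. Chromosome I held 4 of the first 10 combined peaks. They lay at 11254311 to 11254719 (combined number 3, replicate numbers 4 and 8), 11102331 to 11102693 (combined 5, replicates 8 and 3), 2273072 to 2273649 (combined 7, replicates 3 and 50) and 1958370 to 1958736 (combined 10, replicates 19 and 2). Chromosome IV held 3, at 12689291 to 12689662 (combined 6, replicates 6 and 7), 4673338 to 4673689 (combined 8, replicates 10 and 16) and 4167291 to 4167684 (combined 9, replicates 11 and 12). The first peak of chromosome V, at 17845628 to 17845976, was combined number 4, with replicate numbers 5 and 6. The first peak of chromosome X came later, as combined number 31 at 13227748 to 13228073, with replicate numbers 21 and 129. The widest combined interval spanned 2731 bp at chromosome III 7814232 to 7816962. It was entered 3 times, first as number 224, and intervals of 2658 and 2767 bp lay at the same place in replicates 1 and 2. It too was named after its values were seen.

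Combined peaks were unevenly spread over the chromosomes. Chromosome I held 439 peaks, 19.6% of the list (interval 18 to 21.3%), where it made up 15% of the span. This was 1.31 times the expected number (two-sided exact binomial test, adjusted p = 2.6e-08) and 29.2 peaks per Mb. Chromosome III held 369 peaks, 1.2 times the expected number (exact binomial test, adjusted p = 0.00068). The X chromosome held 336 peaks, 15% of the list against 17.7% of the span, a ratio of 0.85 (exact binomial test, adjusted p = 0.0018) and the lowest density, 19 per Mb. Chromosome IV held 349 peaks, a ratio of 0.89 (exact binomial test, adjusted p = 0.031). Chromosomes II (311 peaks, ratio 0.91) and V (433 peaks, ratio 0.93) did not pass the threshold (exact binomial test, adjusted p = 0.083 for both).

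**Figure D3:**
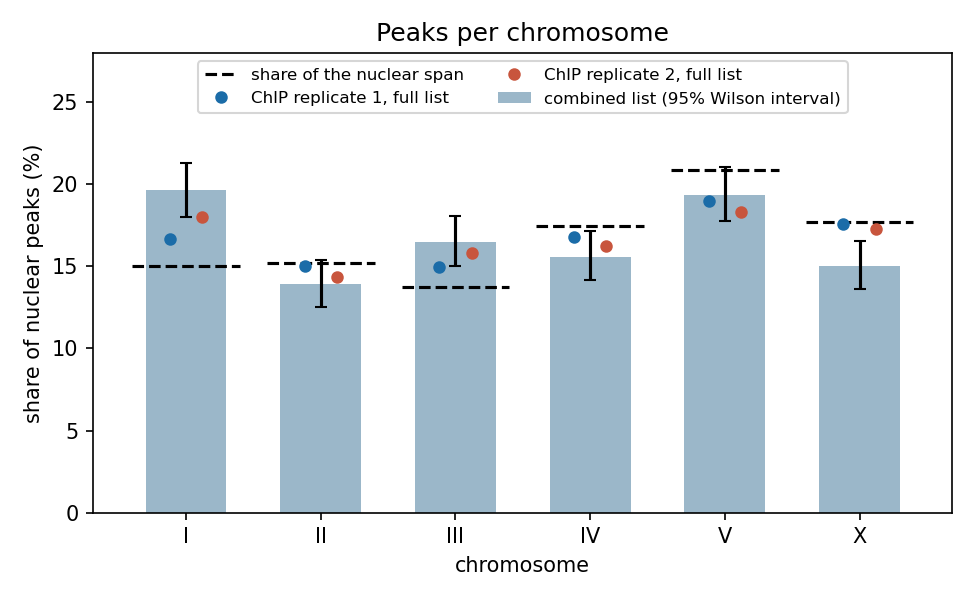
Share of nuclear peaks on each chromosome (y axis, percent; x axis, chromosome). Bars are the combined list with 95% Wilson intervals, dashes are each chromosome's share of the nuclear span, and dots are the full replicate lists; chromosome I stands at 19.6% in the combined list against 15% of the span, and X at 15% against 17.7%.

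Counts in 1 Mb bins, pooled over chromosomes of different density, had a variance 2.42 times their mean, so they varied more than peaks placed independently at 1 even density would. When the 100 bins were exchanged among chromosomes, an alternative added after seeing the data, the excess on chromosome I passed the threshold (ratio 1.31, permutation test, adjusted p = 0.0011). The calls for chromosomes III, IV and X did not (ratios 1.18, 0.92 and 0.83, permutation test, adjusted p = 0.060, 0.32 and 0.054). The call on X was also lost when replicate 1 was left out: the first 2237 nuclear peaks of replicate 2 put 16.6% on X (exact binomial test, adjusted p = 0.18), and the first 2237 of replicate 1 put 14.8% there. In these replicate 2 peaks, lower shares on II (13.5%) and V (17.3%) passed the threshold (exact binomial test, adjusted p = 0.030 and 9.3e-05).

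The middle 33.3% of the chromosomes held 30.6% of combined peaks (685 of 2237; interval 28.7 to 32.6%; two-sided exact binomial test, p = 0.0066). By chromosome, only IV passed the threshold in the binomial test, which takes peaks as independent, with 24.4% of its 349 peaks in the middle (interval 20.1 to 29.1%; exact binomial test, adjusted p = 0.0020 over the 6 chromosomes). On III and V the middle held 33.9% and 33.5%. Over all chromosomes the ratio to expectation was 0.92. With 1 Mb bins exchanged it was 0.93 and the call was lost (permutation test, p = 0.13). The call was also lost without replicate 1, where the middle held 32.5%, a ratio of 0.97 (exact binomial test, p = 0.41). On chromosome IV the call was lost too when 1 Mb bins were exchanged within the chromosome, a test added after seeing the data (ratio 0.76 in 5 of 17 bins, two-sided exact permutation test, adjusted p = 0.15 over the 6 chromosomes). On chromosome IV the middle held 84 of 335 of the first peaks of replicate 2 and 88 of 348 of those of replicate 1 (exact binomial test, adjusted p = 0.0069 and 0.0085).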

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

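The test of peak numbers in this part was chosen after the result was seen, and the test of positions was set beforehand but its criterion was made stricter after its value was seen. Both replicate lists held peaks on mitochondrial DNA, which no comparison above used: 23 in replicate 1 and 25 in replicate 2. They amounted to 1.67 and 1.81 peaks per kb, 8.01 and 13.2 times the nuclear densities of the same lists. The combined list held none. A low place in the lists is argued against as the reason for their absence, since 19 of them in replicate 1 and 24 in replicate 2 were within the first 2237 numbers, the length of the combined list. Their median number was 611 in replicate 1 and 141 in replicate 2, and 10 of the first 100 peaks of replicate 2 were mitochondrial. Whether the positions recur is open. A replicate 1 midpoint lay within 100 bp of 48% of the replicate 2 peaks (interval 30 to 66.5%), where shifts along the molecule gave 32.8% (one-sided permutation test, p = 0.049). The criterion written first, a p under 0.05, was met and by itself would have argued against random places; the added requirement, that the interval exclude the shifted mean, was not met, and the question is left open for that reason. With 1 bp overlap the share was 92%, against 90.7% in shifted lists (one-sided permutation test, p = 0.60); peaks covered 51.5% and 65.2% of the molecule. Removal of mitochondrial peaks by the authors and a high copy number of this DNA were not tested, and no biological explanation was tested.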

How the results depend on the processing

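The shortened replicate 1 list, the expectation from replicate peaks outside the combined list and the exchanges of 1 Mb bins were tests chosen after the result was seen. The overlap between replicates passed its test under each of the 5 other settings, with shares of 14.4 to 32.5% for replicate 1 and 21.8 to 44.6% for replicate 2. Midpoints within 100 bp gave the lowest shares, 14.4% and 21.8%, and the highest ratios to shifted lists, 5.16 and 5.17. With that rule, rho between replicate orders rose to 0.565 over replicate 1 peaks and 0.566 over replicate 2 peaks. Combined peaks found in replicate 1, replicate 2 and both were 86.5%, 59.7% and 59.1% with a reciprocal overlap of 50%, and 98.3%, 80.2% and 78.9% with midpoints within 100 bp. The better-ranked 50% of the replicate lists held 80.2% in replicate 2 and 79.9% in both. The cause was not tested. The excess on chromosome I passed under all 6 other settings of that result, though its ratio fell from 1.31 to 1.17 against replicate peaks outside the combined list. The call on chromosome IV (15.6% of peaks, ratio 0.89) was lost in the better-ranked 50% of combined peaks, where its share was no closer to expectation (15.3%, ratio 0.88), and with peaks within 2 kb merged (16.0%, ratio 0.92). The call on the centres (30.6%, ratio 0.92) was lost in the better-ranked 50% (31.1%, ratio 0.93). The better-ranked 50% holds 1118 peaks in place of 2237, so its tests detect less. With each replicate left out in turn, the share ranged from 13.5 to 13.9% on II, 17.3 to 20.0% on V, 14.8 to 16.6% on X, and 31.2 to 32.5% in the centres; II and V passed without replicate 1. Against replicate peaks outside the combined list, the ratios for III (1.09), IV (0.93) and the centres (0.98) no longer passed. With 1 Mb bins exchanged among chromosomes, those for III (1.18), IV (0.92), X (0.83) and the centres (0.93) no longer passed. No paired analysis was possible because only the ChIP samples had lists of their own, so no replicate block could be fitted with the inputs. Leaving out a replicate gives no overlap between replicates, so that result has no such value. The settings for gene positions, motifs and the transgene's loci were not run. Directions turned only in results that passed no threshold in either setting: the ratio on V was 1.04 against replicate peaks outside the combined list, and the middle of II held 33.6% in the better-ranked 50% and 33.7 to 34.2% with a replicate left out, and that of X held 33.7% without replicate 1 (30.7% without replicate 2), where 33.3% was expected. Depth, which the lists do not give, limits all results to an unknown extent.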

Other observations

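The tests of list length, of the combined order, of close neighbours and of the stretch around the chromosome III peak were chosen after the result, or values related to it, had been seen. Distinct combined regions lay closer together than uniform placement along each chromosome would put them. Of the 2203 regions, 26.5% had another within 5 kb, against a mean of 20.1% in uniformly placed sets (one-sided permutation test, 1000 placements, p = 0.001, the smallest it can give). No explanation was tested: sites called as adjacent intervals, uneven gene density or read mappability, and clustered binding would all give a raised share.

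Combined peaks without a replicate 2 partner (285) outnumbered those without a replicate 1 partner (3). The longer replicate 1 list is argued against as the cause: with that list shortened to the length of the other, 5 combined peaks lacked a replicate 1 partner. Different peak widths are argued against too. Replicate 2 peaks were mostly the wider ones, 600 against 384 bp, which under 1 bp overlap would work against the pattern. With midpoints within 100 bp, 38 combined peaks lacked a replicate 1 partner and 442 a replicate 2 partner. The combined order followed replicate 1 more closely, with a Spearman rho of 0.90 against 0.56 across peaks found in both, a difference of 0.35 (bootstrap interval 0.31 to 0.38). This closer order comes from the same lists as the pattern, so it does not test why the 285 peaks lacked a replicate 2 partner. A heavier weight of replicate 1 in the combined order stays open. So does depth or enrichment that differed between the libraries, which the lists do not give.

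The replicate 2 peak at chromosome III 6478281 to 6478531, number 13 of that list, had no overlapping peak among the 20902 of replicate 1. A combined peak, number 118, lay over it at 6478240 to 6478570. The nearest replicate 1 peak, number 56, began 82 bp farther on, at 6478614, and had its own partner, number 38, in replicate 2. Whether replicate 1 could resolve such neighbours stays open. Among its first 2237 nuclear peaks, 40 neighbouring pairs had midpoints no more than 353 bp apart. At the usual replicate 1 width of 384 bp such pairs overlap each other. The criterion written against poor resolution as the reason, 3 or more such pairs, was met, but overlapping pairs can count towards it. How many of the 40 were separate intervals, as the replicate 2 peaks here are, was not counted. The criterion therefore does not decide the question. The stretch within 20 kb on either side, chosen because it holds this peak, had a median log2 ratio of replicate 1 to replicate 2 numbers of 1.78 over 8 peaks with a partner, where the genome median was 0.10; lists of different lengths shift both values alike. In 6 of the 8 the lower number was in replicate 2, and their best-ordered partners were 7 distinct replicate 1 peaks. The median was at percentile 97.5 of 162 such windows around other peaks among the first 500 of replicate 2. That met the criterion written for a stretch that ranks higher in replicate 2 as a whole. Only 3 of these windows surrounded, as this one does, a leading peak with no partner. They are too few to decide whether the stretch differed between the samples, and the question is left open for that reason. The tagged transgene's own loci, where copy number can differ, were not located on WS220 here, so whether this stretch is one of them was not tested and stays open.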
